A study of Mus musculus with 3 samples.

How the data were processed

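The series holds 3 libraries of 10x Genomics 3' v2 chemistry from sorted mouse marrow cells (live, CD45-positive, lineage-negative, Sca1-positive, Kit-positive), 1 library each of control, vancomycin and vancomycin plus BAP mice, with cells of 3 mice per group in each library per the design text. The mice were described as males of 8 weeks, and about 10000 cells were sorted per group. Vancomycin was given at 200 mg/L, and BAP was butyrate, acetate and propionate at 40, 67.5 and 25.9 mM in the water. Libraries were sequenced on a NextSeq500. The deposited values are whole-number UMI counts per gene and barcode that the authors made with the Cell Ranger count pipeline on the mm10 reference, with no further scaling. The version of Cell Ranger and the annotation release were not given in the sources used here. The 3 matrices had the same 28692 gene rows, in which 67 symbols were shared by several rows, and 0 columns lacked a sample. The matrices hold only barcodes that the authors called as cells, so empty droplets, and with them a direct measure of free RNA, were not available. Ensembl identifiers were matched to an annotation of GRCm38, and 28339 (98.8%) were found.

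Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left out 1, 13 and 11 barcodes of the control, vancomycin and vancomycin plus BAP libraries. Doublet-like barcodes were ranked by their neighbours among simulated doublets, and 0.8% for each 1000 barcodes were left out, 587 (6.85%), 375 (5.48%) and 615 (7.01%). The kept 22583 cells held 43797115, 41542653 and 47573194 UMIs. Kept cells had 1926 to 23348, 1960 to 23425 and 2091 to 41103 UMIs.

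No test was run, since each group had 1 library and cells are not replicates. UMIs were summed per library and scaled to CPM over all genes, and ratios of libraries were taken without a pseudocount. Each ratio has an exact 95% interval for the ratio of 2 Poisson counts, from the conditional binomial, which covers counting error only and neither mice, sorts nor library preparation. The 7449 genes with a mean CPM of at least 10 over the 3 libraries were compared, and genes at least 1.5-fold apart were counted by size. A count of 0 was set against 3 UMIs to give a lower bound. For each of 44 fixed gene lists, the median log2 ratio was set beside 10000 random lists of the same size drawn from 20 bins of mean expression, and members at least 1.3-fold apart were counted. No median was given for the 4 lists with fewer than 3 measured genes. Lists overlap, so their medians are not independent.

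Cells of all libraries were clustered together without batch integration, on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1. A cluster was named after 1 of 13 marker lists when at least 3 markers and 40% of the list were detected in 10% of its cells and 1.5-fold above the other cells, when no other list had as many, and when its 10 leading genes held a marker of that list and no more of any other. These naming thresholds were set after the data were seen. Classes with at least 200 cells in each library were also compared gene by gene, with a minimum mean CPM of 20. S and G2/M scores were computed on cells thinned at random to 3000 UMIs, the 10% point of depth rounded down, which left out 2231 shallower cells. The position of vancomycin plus BAP between the other libraries was its log2 ratio to control over that of vancomycin. Libraries of no effect were simulated by Poisson draws for the correlation that counting error in a shared control gives.

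Genes to be named were fixed by rule before the data were examined, together with the gene lists, markers, minimum expression, comparisons and most alternatives. For vancomycin against control and vancomycin plus BAP against vancomycin the 12 highest and 12 lowest ratios were named, for vancomycin plus BAP against control 6 and 6, and within classes 4 and 4, each with a ratio of at least 1.3, an interval without 1 and the same direction after class standardisation. Predicted genes and pseudogenes were counted but not named. A gene that this rule selected is not reported here. Of each list the members with the largest ratios were eligible, and genes of short-chain fatty acid receptors and transporters and the sort markers were always given. After the first results a further series of genes was drawn by the same rule without immunoglobulin, haemoglobin, neutrophil and B-lineage-like cluster genes.

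Alternatives set beforehand were median-of-ratios scaling, totals without mitochondrial, ribosomal protein, haemoglobin and the 20 most abundant genes, stricter filters (1000 genes, 5% mitochondrial), all barcodes, doublet-like barcodes kept, ratios standardised to one make-up of clusters, equal weight for each cell, minimum CPM of 2 and 50, Leiden resolutions of 0.6 and 1.6, clustering without cell cycle genes, assignment to clusters of the control library, scores not thinned or over 0.1, and other fold limits (1.3 and 2) or split cells for the position. Added after results were seen were removal of the B-lineage-like cluster, cells with no positive cycle score, sums of thinned cells, a correction for transcript length and GC content, a pseudocount of 0.1 CPM, clustering without marker genes, and median-of-ratios scaling for the position and within classes. A pseudocount of 0.1 CPM had been used at first and was replaced by the plain ratio once folds at its edge were seen.

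The counting rule was tested on simulated data, with known folds placed on 50 genes each of the 7449 at the depth of the vancomycin and control libraries. Of genes with a true fold of 1.5, 50% passed the 1.5-fold limit, of those with 1.3 0%, and of those with 2 or 3 100%, while 0 of 7249 unaltered genes passed. The intervals held the true value for 94.97% of genes. This shows counting precision, not differences between mice. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.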

Results

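Single-cell transcriptomes were measured in 3 libraries of haematopoietic stem and progenitor cells sorted from mouse bone marrow, 1 library per group. The sorted population, called LSK, is the live CD45-positive fraction that lacks mature lineage markers and carries Sca1 and Kit, and it holds stem cells together with early multipotent progenitors. Per the design text, each group had 3 male mice aged 8 weeks and about 10000 cells were sorted per group. The sex-linked transcripts argue against male cells, as described below. Control mice had regular water. Vancomycin mice were exposed from before birth to adulthood, through their dams and then directly, to drinking water with 200 mg/L of vancomycin, an antibiotic that acts mainly on Gram-positive gut bacteria. The last group had vancomycin plus BAP, a mixture of the short-chain fatty acids butyrate (40 mM), acetate (67.5 mM) and propionate (25.9 mM), which gut bacteria make from fibre. The deposited barcodes numbered 8567 in the control library, 6847 in the vancomycin library and 8771 in the vancomycin plus BAP library, with 49704595, 45290219 and 53875804 unique molecular identifiers (UMIs). After filtering, 7979, 6459 and 8145 cells were kept, with median depths of 4618, 5440 and 4893 UMIs and medians of 1729, 2127 and 1807 genes per cell. With 1 library per group no difference has a replicate check: intervals are 95% intervals of counting error only, and higher and lower describe these libraries, not the treatments.

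The first comparison, vancomycin against control, addresses how lifelong antibiotic exposure relates to expression in marrow precursors. Genes of mitosis, DNA replication, MHC class I antigen presentation and glycolysis were higher in the vancomycin library, genes of cytosolic ribosomal proteins were lower, and transcripts of plasma cells were present that the control library nearly lacked. Kif2c, a kinesin that corrects chromosome attachment in mitosis, was 2.31-fold (2.05 to 2.59) higher, and Rrm1, the large subunit of the enzyme that makes deoxyribonucleotides, was 2.23-fold (2.13 to 2.34) higher. H2-T23, a non-classical MHC class I molecule, stood 2.10-fold (2.02 to 2.20) higher and Pfkp, a phosphofructokinase of glycolysis, 2.30-fold (2.09 to 2.53) higher. Rpl27, a protein of the large ribosomal subunit, was at 0.482 of the control level (0.456 to 0.510). Of 7449 genes with a mean of at least 10 CPM (UMIs of a gene scaled to one library total), 687 were at least 1.5-fold higher and 41 at least 1.5-fold lower, so that 94.4% of these were higher. The median of all genes was itself 0.18 higher on the log2 scale, and ribosomal protein genes took 28.1% of UMIs against 35.0% in control. With median-of-ratios scaling the counts were 300 higher and 108 lower (73.5% higher, all-gene median -0.01), and with the most abundant genes left out of the totals 339 and 97 (77.8% higher, median 0.02).

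Among the gene lists, G2 and M phase genes had a median log2 ratio of 0.65 (above all 10000 random lists of like size and expression), which is 0.47 above the all-gene median, and 40 of 50 measured genes were at least 1.3-fold higher. Of all 7449 genes, 1790 were at least 1.3-fold higher and 125 at least 1.3-fold lower, the background for such counts of list members. Dlgap5, which organises spindle microtubules, was 2.16-fold (1.93 to 2.41) and Cdc20, an activator of the anaphase-promoting complex, 1.98-fold (1.89 to 2.07) higher. S phase genes had a median of 0.33 (percentile 99.9), with 20 of 44 at least 1.3-fold higher and Mcm3, a subunit of the replicative helicase, at 2.15-fold (2.07 to 2.23). Standardised to one make-up of cell classes, the G2 and M phase median was 0.36. Core and linker histones were mixed, with a median of 0.05 that fell to -0.13 under median-of-ratios scaling, Hist1h4d at 1.66-fold (1.49 to 1.83) and Hist1h2ac at 0.543 of the control level (0.460 to 0.639). Beside these values, a cluster led by the helicase genes Mcm2 to Mcm7 and the replication licensing factor Cdt1 held 17.9% of vancomycin cells, 0.213% of control cells and 0.381% of vancomycin plus BAP cells, and a cluster of nearly 1 library may be that library and not a cell state.

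MHC class I genes, which load and present peptides of the cell's own proteins, had a median of 0.66 (above all 10000 random lists), and 10 of 15 were at least 1.3-fold higher, among them Tap2, a peptide transporter, at 2.08-fold (2.01 to 2.15) and H2-Q6 at 2.01-fold (1.86 to 2.16). The MHC class II list had a median of 0.68 over 8 genes (above all 10000 random lists), with Cd74, the invariant chain, 10.5-fold (9.37 to 11.8), H2-Aa 4.46-fold (3.86 to 5.17) and H2-Ab1 2.24-fold (2.12 to 2.38) higher. The B-lineage-like cluster carried part of this: without it the log2 ratio of Cd74 was 1.5 instead of 3.39, that of H2-Aa was 2.15 instead of 2.16, and the list median was 0.53. The monocyte, macrophage and dendritic cell list shares Cd74, H2-Aa, H2-Ab1 and Ctss with it and had a median of 0.68 (above all 10000 random lists), or 0.40 with a minimum of 2 CPM. Interferon-response genes had a median of 0.29 (percentile 98.6), with 13 of 38 at least 1.3-fold higher and 0 lower, led by the interferon-inducible GTPases Ifi47 at 2.24-fold (2.13 to 2.36) and Gbp2 at 2.22-fold (1.98 to 2.49). Over all 7449 genes, 1790 were at least 1.3-fold higher and 125 lower. Toll-like receptor and inflammasome genes (0.20, percentile 55.9) lay near the all-gene median, with Ifngr1, a receptor chain for interferon gamma, at 1.40-fold (1.34 to 1.46). NF-kappaB and TNF response genes had a median of 0.15 (percentile 40.6), or -0.03 with median-of-ratios scaling, and Icam1 was 1.72-fold (1.53 to 1.94) higher while Ccl4, a chemokine, was at 0.820 of control (0.792 to 0.848).

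Of the lists of metabolic genes, glycolysis and fatty acid oxidation stood above the middle 95% of random lists. Glycolysis genes had a median of 0.49 (above all 10000 random lists), 0.31 above the all-gene median, with 11 of 19 at least 1.3-fold higher, and Pfkl was 1.87-fold (1.77 to 1.97) and Pkm, a pyruvate kinase, 1.61-fold (1.58 to 1.64) higher. Fatty acid oxidation genes had a median of 0.37 (percentile 99.8), with Acadvl, the very-long-chain acyl-CoA dehydrogenase, at 1.72-fold (1.61 to 1.85) and 11 of 22 at least 1.3-fold higher. Cholesterol biosynthesis genes had a median of 0.32 (percentile 89.5), with the lanosterol demethylase Cyp51 at 1.71-fold (1.53 to 1.92). Genes that use short-chain fatty acids had a median of 0.26 (percentile 77.5), with Pcca, a propionyl-CoA carboxylase subunit, at 1.76-fold (1.59 to 1.94). Nuclear genes of oxidative phosphorylation stood apart at -0.04 (percentile 1.16), -0.22 relative to the all-gene median, although Ndufs1 of complex I was 1.90-fold (1.77 to 2.04) and Sdhc of complex II 1.75-fold (1.67 to 1.83) higher. Mitochondrially encoded genes had a median of -0.09 (percentile 11.3) and went both ways, with mt-Nd3 at 1.5-fold (1.45 to 1.56) and mt-Nd4l at 0.537 of control (0.513 to 0.562). Antioxidant genes (0.16, percentile 75.1, and -0.02 with median-of-ratios scaling) included Nfe2l2, the regulator NRF2, at 1.73-fold (1.63 to 1.83).

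Cytosolic ribosomal protein genes were lower, with a median of -0.35 (below all 10000 random lists), -0.52 relative to the all-gene median, and 30 of 75 at least 1.3-fold lower against 1 higher. Rps26 was at 0.514 of control (0.508 to 0.520), Rpl15 at 0.543 (0.535 to 0.553) and Rpl39 at 0.562 (0.559 to 0.565). Fau, which encodes a ribosomal protein fused to a ubiquitin-like protein, was at 0.532 (0.481 to 0.587). Values of single ribosomal protein genes are uncertain, since many have near-identical pseudogene copies that can share reads. Ribosome biogenesis and MYC target genes had a median of 0.22 (percentile 96.4), inside the middle 95% of random lists, with 9 of 26 at least 1.3-fold higher, Bop1 at 1.77-fold (1.64 to 1.90) and Eif4a1, a translation helicase, at 1.70-fold (1.68 to 1.72). Unfolded protein response genes had a median of 0.29 (percentile 96.5), with asparagine synthetase Asns at 1.98-fold (1.74 to 2.25) and the chaperone Hspa5 at 1.70-fold (1.66 to 1.74). Heat shock and dissociation stress genes had one of 0.34 (percentile 98.9). Immediate early genes had a median of 0.28 (percentile 98.6), with 8 of 20 at least 1.3-fold higher, led by the transcription factors Klf4 at 2.42-fold (2.11 to 2.79) and Klf6 at 2.18-fold (2.10 to 2.26). AP-1 and cytokine-signalling suppressors (0.24, percentile 67.9) included the kinase Pim2 at 1.64-fold (1.45 to 1.86) and Socs3 at 1.58-fold (1.43 to 1.74).

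Stem cell and lineage-priming lists lay close to the all-gene median, with single genes well above it. The HSC signature had a median of 0.20 (percentile 62.7), with the endothelial adhesion molecule Esam at 2.17-fold (1.95 to 2.43) and the stem cell regulator Mecom at 2.03-fold (1.82 to 2.26). Megakaryocyte priming had a median of 0.18 (percentile 52.7), with P-selectin, Selp, at 2.78-fold (2.48 to 3.12) and the integrin Itga2b at 2.07-fold (1.92 to 2.22). Adhesion and niche retention genes had one of 0.22 (percentile 77.7). Lymphoid priming had a median of 0.18 (percentile 68.2), with the receptor Flt3 at 1.83-fold (1.76 to 1.91) and the terminal transferase Dntt at 1.64-fold (1.59 to 1.68). The immunoglobulin heavy chain Ighm in this list was 10.2-fold (10.0 to 10.5) higher, but its log2 ratio of 3.35 became 0.39 without the B-lineage-like cluster. Granulocyte-monocyte priming (0.11, percentile 40.3) included the hexokinase Hk3 at 1.90-fold (1.75 to 2.06) and myeloperoxidase, Mpo, at 1.41-fold (1.39 to 1.43). Erythroid priming (0.04, percentile 4.91; 0.255 standardised to one class make-up) included the carbonic anhydrases Car2 at 1.68-fold (1.65 to 1.71) and Car1 at 0.810 of control (0.769 to 0.853). HOX and stem cell transcription factors had a median of 0.03 (percentile 3.79), with Erg at 1.40-fold (1.31 to 1.49). Quiescence, p53 and CDK inhibitor genes had one of 0.14 (percentile 35.2), with Cdkn2c at 1.69-fold (1.56 to 1.83). With median-of-ratios scaling the megakaryocyte priming median lay within 0.01 of 0, and the medians of granulocyte-monocyte and erythroid priming, HOX genes and quiescence lay below it, at -0.07, -0.14, -0.15 and -0.04. Of the sort markers, Ly6a, which encodes Sca1, was 1.88-fold (1.76 to 2.0), Ptprc, which encodes CD45, 1.21-fold (1.15 to 1.27) and Kit 1.07-fold (1.02 to 1.12) higher (list median 0.28, percentile 72.5), and Kit lay lower, at a log2 ratio of -0.08, with median-of-ratios scaling. The B-lineage-like cells carried part of the Ly6a difference, whose log2 ratio was 0.57 instead of 0.91 without them.

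Chromatin lists lay near the all-gene median. Histone deacetylases and acetyltransferases, the former being known targets of butyrate, had a median of 0.22 (percentile 68.6), with Hdac8 at 2.20-fold (1.95 to 2.48) and Hdac1 at 1.74-fold (1.64 to 1.84) and 7 of 21 at least 1.3-fold higher. Polycomb, Trithorax and DNA methylation genes had a median of 0.12 (percentile 11.1; -0.06 with median-of-ratios scaling). SWI/SNF, remodelling and bromodomain genes had one of 0.16 (percentile 55.2; -0.02). The first list included Rbbp7 at 1.53-fold (1.49 to 1.58) and the other the remodeller Smarca4 at 1.36-fold (1.29 to 1.43). Aryl hydrocarbon and nuclear receptor genes had a median of 0.09 (percentile 20.9; -0.09), with the retinoid receptor Rxrb at 1.5-fold (1.42 to 1.6). Of the short-chain fatty acid receptors and transporters, 2 of 8 genes passed the expression minimum, too few for a median. The receptor Ffar2 was 1.18-fold (1.08 to 1.28) and the transporter Slc16a1 1.53-fold (1.38 to 1.69) higher. Hcar2, a receptor for butyrate and niacin, had 37 UMIs in control and 89 in vancomycin, 2.54-fold (1.71 to 3.83) higher, and Slc16a3 was 1.27-fold (1.01 to 1.6) higher. Slc16a7 was at 0.941 of control (0.776 to 1.14), and Ffar3, Olfr78 and Slc5a8 had 0 UMIs in both libraries, which allows up to 0.0685 CPM in control and 0.0722 CPM in vancomycin.

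Transcripts of mature cells that the gate should remove differed most. Igkc, the kappa light chain constant region, was 118-fold (113 to 122) and Jchain, which joins antibody polymers, 79.9-fold (74.3 to 86.0) higher. Igha, the IgA heavy chain, had 1 UMI in control and a ratio of 43931 (7884 to 1735238). The lambda chains Iglc1, Iglc2 and Iglc3 stood at 2587-fold (1108 to 7969), 332-fold (231 to 496) and 104-fold (56.3 to 218), with 5 control UMIs behind Iglc1, and Ighg2c, with 2 control UMIs, at 683-fold (189 to 5647). The B lineage list had a median of 6.88, but 3 of its 15 genes passed the minimum of 10 CPM, Iglc2 through the exposed libraries alone, and with a minimum of 2 CPM the median was 0.71. A B-lineage-like cluster, led by Igkc, Jchain and Igha, held 58 vancomycin cells, 94 vancomycin plus BAP cells and 1 control cell. That control cell held 2909 Igkc, 710 Jchain and 28 Iglc2 UMIs, while control cells of the unnamed clusters had a mean of 0.0091 Igkc UMIs. The control levels of Igkc, Jchain and Iglc2 thus rested largely on 1 cell, which the counting intervals do not cover. Prg2, an eosinophil granule protein that is also among the genes leading the B-lineage-like cluster, was 49.4-fold (29.8 to 88.8) higher, with a log2 ratio of 0.62 instead of 5.63 without that cluster. Haemoglobin genes had a median of 2.93, where 3 of 6 measured genes passed the minimum through the exposed libraries alone, and of 0.95 with a minimum of 2 CPM, with Hba-a2 at 48.4-fold (30.5 to 82.1), Hbb-bs at 33.7-fold (27.7 to 41.3) and Hba-a1 at 30.2-fold (21.4 to 43.8). Of all cells, 10 held 82.7% of the haemoglobin UMIs of the vancomycin library. The neutrophil gene S100a9 was 56.4-fold (37.8 to 88.4) higher, and 2 cells held 96.1% of the vancomycin UMIs of S100a8, S100a9, Ngp and Camp. Of the mature neutrophil list 2 genes were measured, as of the stromal and endothelial list, so neither has a median. Mast cell, basophil and eosinophil genes had a median of 0.10 (percentile 19.2; -0.08 with median-of-ratios scaling and 0.34 standardised to one class make-up). The basophil proteases Prss34 and Mcpt8 were 4.45-fold (4.02 to 4.94) and 2.49-fold (2.32 to 2.67) higher, with 79.3% of their UMIs in 6 cells. Both were lower among cells with no positive cell cycle score (log2 ratios of -1.54 and -1.09). The T and NK lineage list had a median of -0.43 (percentile 0.0300; -0.04 standardised to one class make-up), with the T cell receptor constant region Trbc1 at 0.436 of control (0.377 to 0.503; log2 ratio -1.20, or -0.18 standardised). Type 2 innate lymphoid and early T lineage genes had a median of 0.23 (percentile 67.5).

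Of single genes outside these groups, Mid1, an X-linked ubiquitin ligase of microtubules, was 8.13-fold (6.74 to 9.88) higher, the endosomal GTPase Rab21 3.01-fold (2.67 to 3.41), the platelet glycoprotein Gp5 2.76-fold (2.41 to 3.16), the cytokinesis kinesin Kif20a 2.76-fold (2.49 to 3.08), the spindle checkpoint kinase Bub1b 2.5-fold (2.27 to 2.75) and the cold-shock protein Ybx3 2.52-fold (2.42 to 2.62). Also higher were Cenpv at 2.98-fold (2.70 to 3.29) and Zbtb8b at 2.96-fold (2.67 to 3.28). Lower genes were Snhg20, a host gene of small nucleolar RNAs, at 0.455 of control (0.420 to 0.492), the histone gene Hist4h4 at 0.457 (0.415 to 0.502) and Wdr89 at 0.490 (0.474 to 0.506). Xist, the non-coding RNA that coats the inactive X chromosome of female cells, was at 0.518 of control (0.513 to 0.523), with 3061, 1585 and 2827 CPM in control, vancomycin and vancomycin plus BAP, and was found in 99.9%, 99.6% and 99.8% of cells. Its antisense partner Tsix was 1.79-fold (1.65 to 1.95) higher, and reads of a gene and its antisense partner cannot be told apart where counting ignores strand. The sex-linked list had 1 measured gene, Xist. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0 UMIs in control, which allows up to 0.0685 CPM, to 6 in vancomycin and to 5 in vancomycin plus BAP, although the design text gives male mice. In the GRCm38 annotation, the build known as mm10, Kif2c (ENSMUSG00000028678) on chromosome 4 from 117159639 to 117182639 and Rrm1 (ENSMUSG00000030978) on chromosome 7 from 102441695 to 102469771 are protein-coding genes. The MHC genes are H2-T23 (ENSMUSG00000067212) on chromosome 17 from 36029773 to 36032855 and H2-Aa (ENSMUSG00000036594) on chromosome 17 from 34282744 to 34287823. Protein-coding are also Pfkp (ENSMUSG00000021196) on chromosome 13 from 6579768 to 6648777 and Esam (ENSMUSG00000001946) on chromosome 9 from 37528078 to 37538319. The sort markers are Ly6a (ENSMUSG00000075602) on chromosome 15 from 74994877 to 74998031 and Kit (ENSMUSG00000005672) on chromosome 5 from 75574916 to 75656722. The X chromosome holds Rpl39 (ENSMUSG00000079641) on chromosome X from 37082520 to 37085402 and Mid1 (ENSMUSG00000035299) on chromosome X from 169685199 to 170005736. The immunoglobulin constant region gene Igha (ENSMUSG00000095079) lies on chromosome 12, 113254830 to 113260236, Igkc on chromosome 6, 70726435 to 70726966, Jchain on chromosome 5, 88519809 to 88527891 and Xist on chromosome X, 103460366 to 103483254. Counts are per gene and do not separate exons, introns or UTRs.

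**Figure D1:**
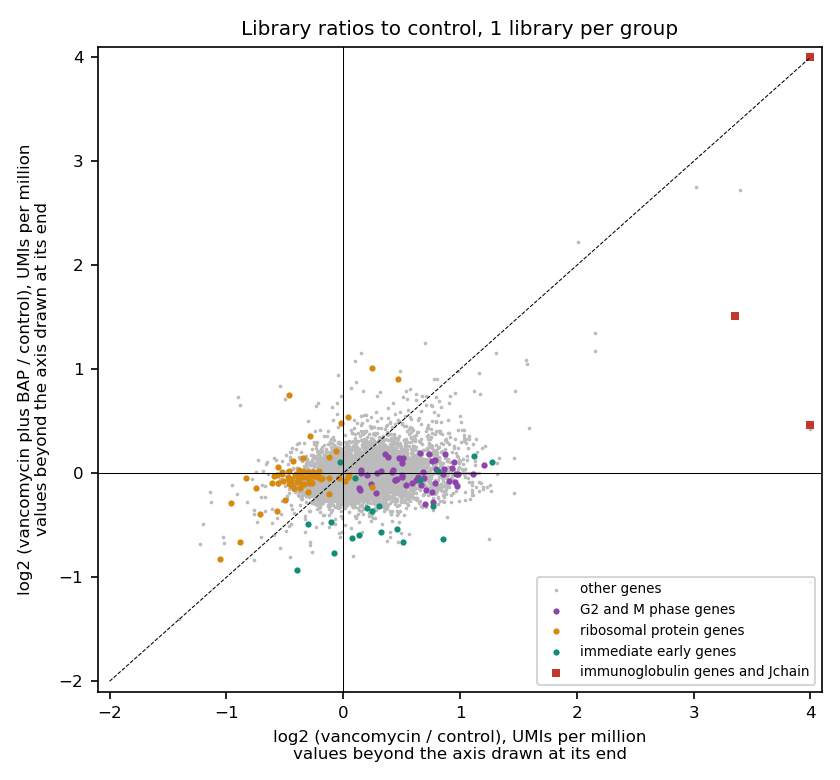
Log2 ratio to control of each of the 7449 measured genes in the vancomycin library (horizontal axis) and in the vancomycin plus BAP library (vertical axis), with values beyond an axis drawn at its end. Most genes that are higher in vancomycin lie near 0 on the vertical axis, and immunoglobulin and haemoglobin genes are high on both.

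The second comparison, vancomycin plus BAP against vancomycin, addresses what differs when short-chain fatty acids are given with the antibiotic. It uses the same vancomycin library as the first comparison, so opposite values in these comparisons are not independent. Medians of the lists for the cell cycle, immediate early response, MHC class I, heat shock and granulocyte-monocyte priming lay below the middle 95% of random lists, and that of ribosomal protein genes above it. Klf2, a transcription factor of quiescence and lymphocyte traffic, was at 0.356 of the vancomycin level (0.341 to 0.371), the mitotic kinase Plk1 at 0.389 (0.357 to 0.422), Rrm1 at 0.397 (0.379 to 0.416) and Pfkp at 0.393 (0.356 to 0.433). Rpl9 was 2.33-fold (2.26 to 2.39) higher and Rpl39 1.73-fold (1.72 to 1.74) higher. Of the 7449 genes, 52 were at least 1.5-fold higher and 760 at least 1.5-fold lower, with an all-gene median of -0.18. With median-of-ratios scaling 112 were higher and 337 lower, and with the most abundant genes left out of the totals 106 and 353.

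Immediate early genes had the lowest median of any list with 10 or more measured genes, -0.71 (below all 10000 random lists), -0.53 relative to the all-gene median, and 16 of 20 were at least 1.3-fold lower, with the orphan nuclear receptor Nr4a1 at 0.444 of vancomycin (0.411 to 0.479) and Klf4 at 0.446 (0.391 to 0.509). Such counts of list members stand against an all-gene median of -0.18, with 760 of 7449 genes at least 1.5-fold lower. A 1.3-fold limit takes in at least as many of all genes. G2 and M phase genes had a median of -0.65 (below all 10000 random lists; -0.27 standardised to one class make-up), with 38 of 50 lower. S phase genes had one of -0.47 (below all 10000 random lists; -0.28 standardised), with 26 of 44 lower and the replication factor Cdc45 at 0.404 (0.366 to 0.445). Ribosome biogenesis genes (-0.41, below all 10000 random lists), heat shock genes (-0.47, percentile 0.115; 5 of 9 lower), cholesterol biosynthesis (-0.44, percentile 0.565) and glycolysis (-0.36, percentile 0.650) were also low, with Hspa5 at 0.461 (0.449 to 0.473) and Cyp51 at 0.478 (0.425 to 0.537). MHC class I genes had a median of -0.46 (percentile 0.0800), with 9 of 15 at least 1.3-fold lower and the peptide-trimming protease Erap1 at 0.492 (0.446 to 0.542). Medians of other immune lists were, for interferon-response genes, -0.31 (percentile 0.930), monocyte, macrophage and dendritic cell genes -0.55 (percentile 0.170) and MHC class II genes -0.21 (percentile 40.1). Granulocyte-monocyte priming had a median of -0.35 (percentile 0.315), with 10 of 23 lower, Mpo at 0.477 (0.470 to 0.484) and cathepsin G, Ctsg, at 0.492 (0.482 to 0.502). Fatty acid oxidation (-0.37, percentile 0.340), NF-kappaB (-0.27, percentile 13.4), SWI/SNF (-0.29, percentile 2.63) and mast cell, basophil and eosinophil genes (-0.31, percentile 15.8) stood below the all-gene median as well.

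Ribosomal protein genes had a median of 0.31 (above all 10000 random lists), with 26 of 75 at least 1.3-fold higher and 0 lower. Histone genes had a median of 0.14 (percentile 99.98), with Hist1h2ac 2.91-fold (2.5 to 3.39), and outside that list Hist1h2bb 2.32-fold (2.01 to 2.67) and Hist1h2bg 1.86-fold (1.64 to 2.11) higher. Mitochondrially encoded genes had a median of 0.14 (percentile 97.6), with mt-Nd4l 3.09-fold (2.96 to 3.22) higher. T and NK lineage genes had one of 0.26 (percentile 99.8), or -0.18 when standardised to one class make-up. Gstp1, a glutathione transferase, was 2.0-fold (1.84 to 2.18), Car1 1.75-fold (1.67 to 1.83), Xist 1.78-fold (1.77 to 1.80), Snhg20 1.95-fold (1.80 to 2.11), Snhg12 1.81-fold (1.71 to 1.92), Ccdc85b 1.99-fold (1.78 to 2.22) and Hist4h4 1.81-fold (1.64 to 1.99) higher. The lambda chain Iglc3 was 6.81-fold (6.37 to 7.28) higher while Ighm was at 0.280 of vancomycin (0.276 to 0.283), with a log2 ratio of -0.23 instead of -1.84 without the B-lineage-like cluster. Iglc2 was at 0.351 (0.338 to 0.365), and Ighg2c, with 1296 UMIs in vancomycin and 0 with BAP, at least 495-fold lower. The 58 vancomycin and 94 vancomycin plus BAP cells of that cluster had means of 150 and 38.4 Iglc2 UMIs. HSC-like cells had 0.062 and 0.0046. Immunoglobulin ratios can thus depend on which few cells were caught, which the counting intervals do not cover. The B lineage list had a median of -0.45, or -0.02 with a minimum of 2 CPM. S100a8 and S100a9 were at 0.0231 (0.0175 to 0.0300) and 0.0238 (0.0165 to 0.0333) of vancomycin, where 2 cells held most of these transcripts. Other lower genes were the tubulin Tuba1c at 0.272 (0.249 to 0.297), Gp5 at 0.318 (0.277 to 0.365), the kinesin Kif22 at 0.371 (0.345 to 0.398) and the nucleoporin Nup93 at 0.387 (0.353 to 0.424). Past these lay Chtf8 at 0.395 (0.368 to 0.424) and the RNA polymerase II subunit Polr2b at 0.397 (0.365 to 0.431).

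The other lists lay within or near the ranges of random lists. The HSC signature had a median of -0.06 (percentile 93.2), lymphoid priming -0.05 (percentile 91.0), megakaryocyte priming -0.12 (percentile 73.6), erythroid priming -0.23 (percentile 35.0), HOX genes -0.06 (percentile 92.1), quiescence -0.11 (percentile 79.0), adhesion -0.16 (percentile 48.5) and sort markers -0.23 (percentile 39.4). Histone deacetylases and acetyltransferases had a median of -0.17 (percentile 62.7), with Hdac1 at 0.535 (0.506 to 0.565), Polycomb genes -0.22 (percentile 35.0), oxidative phosphorylation -0.07 (percentile 41.4), antioxidant genes -0.13 (percentile 42.9) and the unfolded protein response -0.21 (percentile 21.6). Toll-like receptor genes had a median of -0.13 (percentile 70.8), aryl hydrocarbon receptor genes -0.16 (percentile 57.1), cytokine-signalling suppressors 0.01 (percentile 96.2), short-chain fatty acid use -0.23 (percentile 33.0), haemoglobin -0.14 (percentile 71.2) and type 2 innate lymphoid genes 0.03 (percentile 91.4). With median-of-ratios scaling the medians of the HSC, lymphoid, megakaryocyte, HOX, quiescence, antioxidant, toll-like receptor, oxidative phosphorylation and haemoglobin lists were above 0. Ffar2 was at 0.919 of vancomycin (0.847 to 0.997), with a ratio of 1.02 under median-of-ratios scaling, Slc16a1 at 0.673 (0.611 to 0.741), Hcar2 at 0.393 (0.263 to 0.576), Slc16a3 at 0.659 (0.519 to 0.835) and Slc16a7 at 1.05 (0.866 to 1.26). Ffar3 had 1 UMI, and Olfr78 and Slc5a8 had 0. Kit was at 0.932 (0.892 to 0.975; log2 0.05 with median-of-ratios scaling), Ly6a at 0.850 (0.805 to 0.898) and Ptprc at 0.793 (0.756 to 0.832).

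The third comparison, vancomycin plus BAP against control, addresses what separates mice given both from mice given neither. The libraries were closer: 73 genes were at least 1.5-fold higher and 27 at least 1.5-fold lower, with an all-gene median of -0.01, and with median-of-ratios scaling 68 and 35. The medians of immediate early genes and granulocyte-monocyte priming lay below all 10000 random lists, and those of MHC class II, lymphoid priming and HSC genes above them. Of these lists 10 of 20 and 8 of 23 genes were at least 1.3-fold lower, and 4 of 8, 6 of 18 and 5 of 16 at least 1.3-fold higher. Btg2, an antiproliferative factor, was at 0.525 of control (0.508 to 0.542) and Junb, an AP-1 subunit, at 0.588 (0.575 to 0.602). Immediate early genes had a median of -0.42. Granulocyte-monocyte priming had a median of -0.24, with Ms4a3 at 0.632 (0.596 to 0.671), Ctsg at 0.636 (0.623 to 0.650) and Mpo at 0.671 (0.661 to 0.682). Standardised to one class make-up this median was -0.16, and within granulocyte-monocyte-primed-like cells it was -0.04. Esam was 1.73-fold (1.55 to 1.94) higher and Procr, the protein C receptor of stem cells, 1.40-fold (1.24 to 1.58), with an HSC median of 0.17 (0.06 standardised to one class make-up). Lymphoid priming had a median of 0.16 (0.08 standardised), with Dntt at 1.58-fold (1.54 to 1.62). Its member Ly6d was 4.68-fold (4.08 to 5.37), with a log2 ratio of 0.99 instead of 2.23 without the B-lineage-like cluster. The MHC class II median was 0.35, or 0.21 without that cluster and 0.13 standardised to one class make-up, with H2-Aa 2.54-fold (2.18 to 2.97) higher.

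MHC class I genes had a small median of 0.14 (percentile 99.98), with H2-Q4 at 1.68-fold (1.54 to 1.82). Interferon-response genes had one of -0.02 (percentile 32.6). G2 and M phase genes lay at -0.01 (percentile 57.3), S phase genes at -0.13 (below all 10000 random lists; 0.02 standardised to one class make-up), and ribosome biogenesis at -0.14 (below all 10000 random lists; -0.04 standardised). Also low were oxidative phosphorylation at -0.11 (below all 10000 random lists), SWI/SNF genes at -0.11 (percentile 0.120), heat shock genes at -0.13 (percentile 2.40) and cholesterol biosynthesis at -0.21 (percentile 0.01), with squalene epoxidase, Sqle, at 0.741 of control (0.675 to 0.814). Histones (0.09, percentile 99.9), quiescence (0.10, percentile 99.8; -0.0023 standardised to one class make-up), megakaryocyte priming (0.11, percentile 99.6; 0.02 standardised), the unfolded protein response (0.08, percentile 99.4; -0.03 without the B-lineage-like cluster), glycolysis (0.06, percentile 97.46) and type 2 innate lymphoid genes (0.28, percentile 99.8) stood above most random lists. Among their members Hist1h2ap was 2.38-fold (2.22 to 2.56), Pgk1, a glycolytic kinase, 1.98-fold (1.74 to 2.25) and Gata3, a T lineage factor, 1.45-fold (1.3 to 1.61) higher. Ribosomal protein genes had a median of -0.03 (percentile 20.04) and went both ways, with Rps27 2.02-fold (1.92 to 2.12) and Rpl35 1.87-fold (1.85 to 1.90) higher and Rpl27 at 0.565 of control (0.536 to 0.594). B lineage (6.43) and haemoglobin (2.84) medians were high, as with vancomycin alone, but were 0.70 and 0.77 with a minimum of 2 CPM, and 9 cells held 82.8% of the haemoglobin UMIs. Single genes were Igkc at 86.4-fold (83.3 to 89.6), Jchain at 100.2-fold (93.2 to 108), Igha, from 1 control UMI, at 41196-fold (7394 to 1627198), Iglc1 at 1220.0-fold (523 to 3759), Iglc2 at 117-fold (81.0 to 174) and Iglc3 at 709-fold (385 to 1478). Here too the control levels of Igkc, Jchain and Iglc2 rested largely on 1 cell. T and NK genes lay at -0.27 (percentile 0.120) and monocyte, macrophage and dendritic cell genes at 0.26 (above all 10000 random lists). The latter median was 0.11 without the B-lineage-like cluster, 0.14 standardised to one class make-up and 0.02 with a minimum of 2 CPM.

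Within 0.1 of 0 were fatty acid oxidation (0.03, percentile 86.5), short-chain fatty acid use (-0.04, percentile 29.8), mitochondrially encoded genes (0.02, percentile 87.7), antioxidant genes (0.03, percentile 90.5), toll-like receptor genes (0.04, percentile 84.5), NF-kappaB genes (-0.02, percentile 38.1) and aryl hydrocarbon receptor genes (-0.01, percentile 49.3). Histone deacetylases and acetyltransferases (0.01, percentile 72.2), Polycomb genes (-0.05, percentile 9.50), HOX genes (-0.02, percentile 38.0), adhesion genes (0.01, percentile 72.2), erythroid priming (0.04, percentile 85.2), cytokine-signalling suppressors (0.05, percentile 86.0), mast cell, basophil and eosinophil genes (-0.01, percentile 55.3) and sort markers (-0.01, percentile 56.4) were within it too. Under median-of-ratios scaling the adhesion, antioxidant, fatty acid oxidation, deacetylase and mitochondrially encoded medians lay below 0. Ffar2 was at 1.08 (0.995 to 1.18) times control, Slc16a1 at 1.03 (0.925 to 1.14), Hcar2 at 0.995 (0.620 to 1.6), Slc16a3 at 0.835 (0.650 to 1.07) and Slc16a7 at 0.984 (0.820 to 1.18), and each of these intervals includes 1. Kit was at 0.996 (0.953 to 1.04) times control, Ptprc at 0.960 (0.913 to 1.01) and Ly6a at 1.6 (1.5 to 1.70), the last with a log2 ratio of 0.28 instead of 0.67 without the B-lineage-like cluster. Mid1 was 6.75-fold (5.6 to 8.21) and Gstp1 2.23-fold (2.04 to 2.43) higher, as was Tnfsf13os at 2.23-fold (1.99 to 2.5). Prss34 was 2.26-fold (2.02 to 2.52) higher, but 5 cells held 72.8% of the Prss34 and Mcpt8 UMIs, and its log2 ratio was -0.0868 in cells with no positive cell cycle score. S100a8 was at 0.485 of control (0.347 to 0.673) from 110 and 58 UMIs, with a log2 ratio of -1.04, or -0.31 standardised, and 1 control cell held 36.8% of the control UMIs of S100a8, S100a9, Ngp and Camp. Lower too were the chromatin protein Hmga2 at 0.563 (0.514 to 0.616), Rnaset2a at 0.571 (0.526 to 0.620) and the mast cell protease Cpa3 at 0.578 (0.534 to 0.625). In GRCm38, the response genes named here are Klf2 (ENSMUSG00000055148) on chromosome 8 from 72319033 to 72321656, Btg2 (ENSMUSG00000020423) on chromosome 1 from 134075170 to 134079120 and Junb (ENSMUSG00000052837) on chromosome 8 from 84974484 to 84978718. The protein-coding genes Rpl9 (ENSMUSG00000047215) on chromosome 5 from 65388364 to 65391444 and Tuba1c (ENSMUSG00000043091) on chromosome 15 from 99029891 to 99038110 follow. The receptor is Ffar2 (ENSMUSG00000051314) on chromosome 7 from 30818348 to 30823775 and the transporter Slc16a1 (ENSMUSG00000032902) on chromosome 3 from 104638668 to 104658462.

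**Figure D2:**
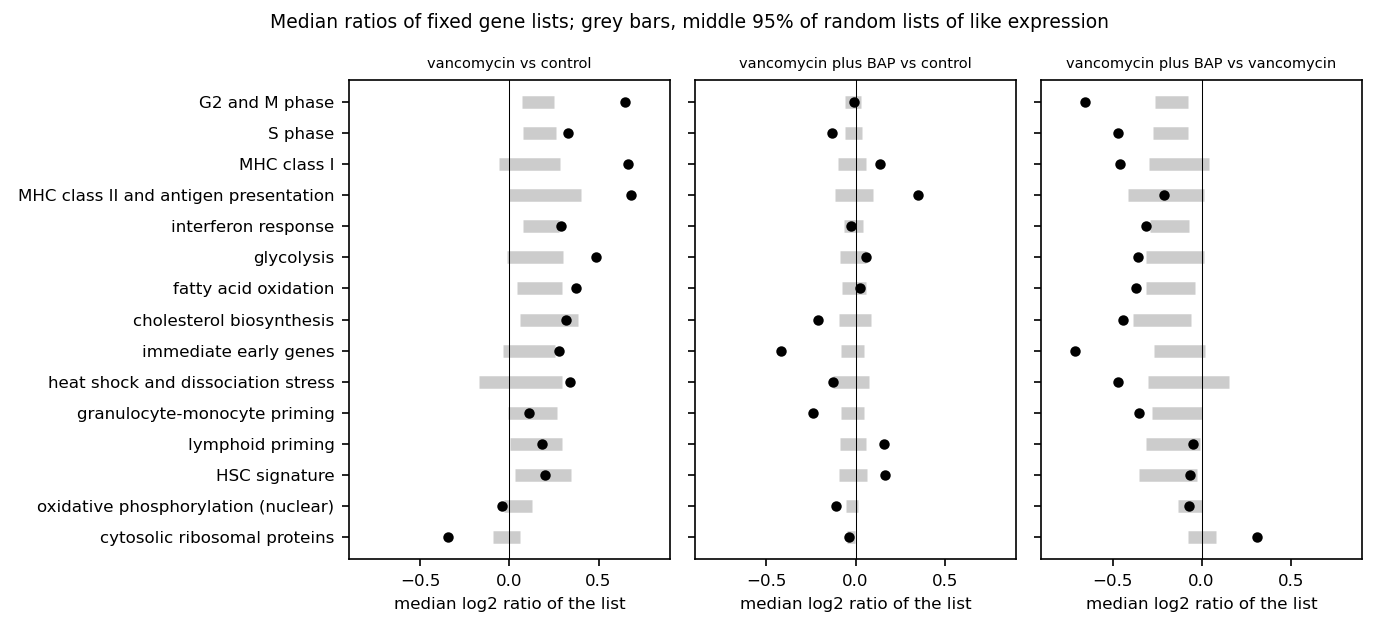
Median log2 ratio of 15 gene lists (points) in each of the 3 comparisons, with grey bars for the middle 95% of medians of random lists of like size and expression. G2 and M phase genes lie at 0.65 in vancomycin against control and at -0.65 in vancomycin plus BAP against vancomycin, and ribosomal protein genes at -0.35 and 0.31. Both comparisons use the same vancomycin library, so these opposite values are not independent.

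Over the 728 genes at least 1.5-fold apart between vancomycin and control, the vancomycin plus BAP library stood at a median position of 0.0496 (interquartile range -0.0978 to 0.257) on a scale from 0 at control to 1 at vancomycin. Of these genes, 643 (88.3%) were nearer control and 15 lay at or beyond vancomycin. The 687 higher genes had a median position of 0.0412 and the 41 lower genes one of 0.294. The genes were picked by the ratio of the 1 vancomycin library to control, which is also the denominator. A deviation particular to that library would place the vancomycin plus BAP library near 0 with or without an effect of BAP. Both exposed libraries were set against the same control library. Of the genes at least 1.5-fold higher, 43 were shared, and of the lower genes 9. In 20 simulations of libraries with no effect, which share the control, a mean of 0 genes was shared in each direction, and independent lists would share 6.73 and 0.149. The former leaves out the effects and any deviation of the control library beyond counting error. The latter leaves out the shared control, so neither is the value expected without a shared effect. Across genes, which are not independent replicates, the log2 ratios to control had Pearson's r = 0.670 and a covariance of 0.106, where simulated libraries with no effect gave 0.505 and 0.00169. Without 26 immunoglobulin, haemoglobin and other mature cell genes, r was 0.233 and the covariance 0.0118. The simulations hold counting error only, so they leave out what mice, sort or preparation of the control library add to both ratios. No simulated value is set beside those without the 26 genes. With 1 control library, part of the overlap and of the correlation may come from the shared control.

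Clustering of all kept cells gave 18 clusters, of which 9 matched a marker list. HSC-like cells (2 clusters) made up 15.3% (14.5 to 16.1%) of control, 26.0% (24.9 to 27.1%) of vancomycin and 24.0% (23.1 to 24.9%) of vancomycin plus BAP cells. Lymphoid-primed-like cells made up 10.0% (9.38 to 10.7%), 8.41% (7.74 to 9.11%) and 10.5% (9.86 to 11.2%). Granulocyte-monocyte-primed-like cells made up 4.70% (4.25 to 5.19%), 4.06% (3.59 to 4.57%) and 2.90% (2.54 to 3.29%), and megakaryocyte-primed-like cells 11.9% (11.2 to 12.6%), 12.8% (11.97 to 13.6%) and 11.1% (10.4 to 11.8%). Erythroid-primed-like cells made up 3.36% (2.97 to 3.78%), 1.94% (1.61 to 2.30%) and 2.15% (1.84 to 2.49%), T or NK-like cells 0.890% (0.696 to 1.12%), 0.449% (0.301 to 0.644%) and 0.798% (0.616 to 1.02%), and B-lineage-like cells 0.0125% (0.000317 to 0.0698%), 0.898% (0.683 to 1.16%) and 1.15% (0.934 to 1.41%). The 9 unnamed clusters held 53.9% (52.8 to 55.0%), 45.5% (44.3 to 46.7%) and 47.4% (46.3 to 48.5%). The sort gate and the greater depth of the vancomycin library can set such shares. The HSC-like share was higher in both exposed libraries under each of 7 other clusterings, but the difference of vancomycin from control ranged from 10.7 down to 1.23 percentage points, and the order of the exposed libraries turned in 6 of the 7. The class itself changed size: it held 18.8% of control cells with the clusters of the control library and 4.18% with doublet-like barcodes kept. These differences are thus not of one set of cells.

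Several unnamed clusters were mostly of some libraries. A cluster led by Clec4e, Osm and Hmga2 held 17.0% of control, 1.46% of vancomycin and 11.3% of vancomycin plus BAP cells, and one led by Irf8, Ung and Tyrobp 12.4%, 1.84% and 9.26%. A mitotic cluster led by Ube2c and Plk1 held 5.31%, 11.1% and 5.56%, and a small cluster led by the interferon-response genes Cxcl10, Ifit3 and Ifit1 0.476%, 0.495% and 0.479%.

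**Figure D3:**
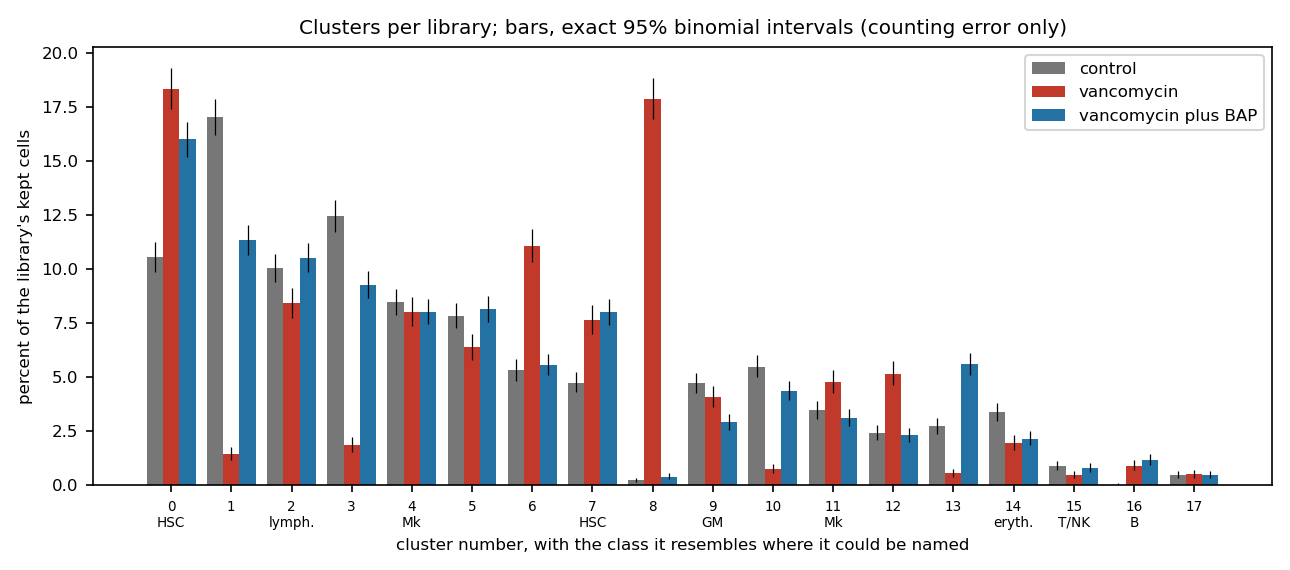
Percent of kept cells of each library in each of the 18 clusters, as bars starting at 0 with exact 95% binomial intervals (counting error only). The cluster numbered 8 holds 17.9% of vancomycin cells and 0.213% of control cells.

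**Figure D4:**
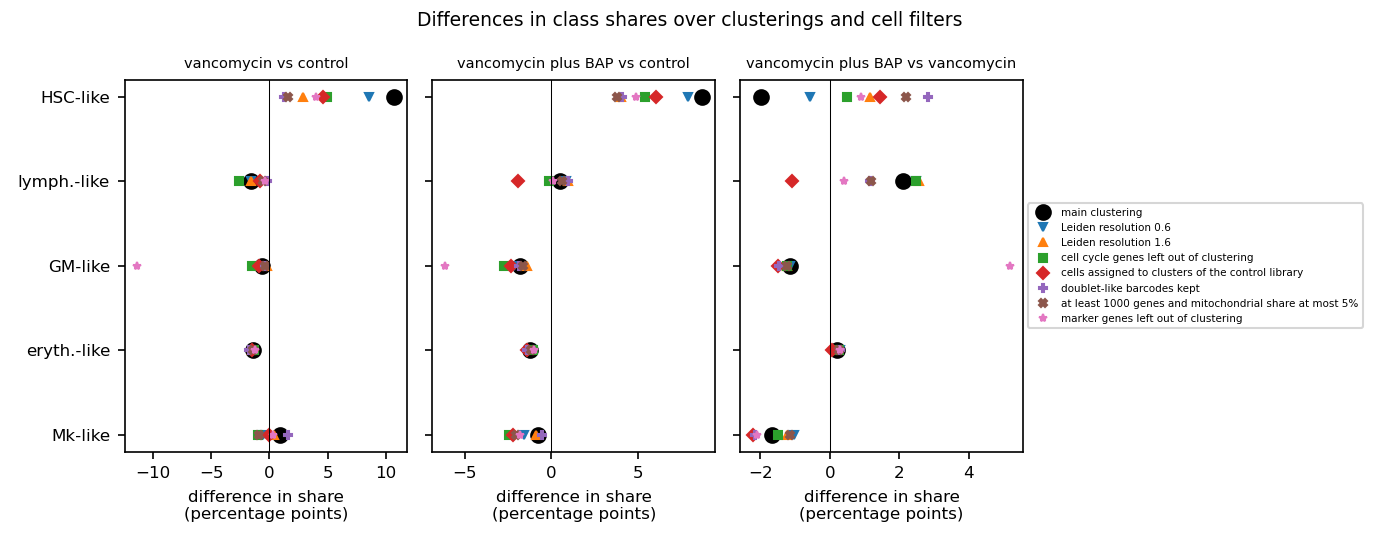
Difference between libraries in the share of cells of 5 named classes, in percentage points, for the main clustering and 7 alternatives. HSC-like cells are above 0 against control in all 8 settings for both exposed libraries, with a span from 1.23 to 10.7 points for vancomycin.

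Cells with a positive S or G2/M score, at 3000 UMIs per cell, made up 57.0% (55.8 to 58.1%) of control, 61.6% (60.3 to 62.8%) of vancomycin and 48.0% (46.8 to 49.1%) of vancomycin plus BAP cells, after 1167, 358 and 706 shallower cells were left out. Without thinning the shares were 50.6%, 59.0% and 45.6%, and 18.9%, 13.6% and 16.9% of cells lay within 0.05 of the threshold, so the classes are ranges of a score. Within HSC-like cells 4.67%, 9.57% and 4.13% were positive, and within granulocyte-monocyte-primed-like cells 91.6%, 97.7% and 93.6%. With scores over 0.1 these became 0.4%, 2.70% and 0.658%, and 71.0%, 90.5% and 74.4%. Thinning kept 750 of 1218, 1484 of 1677 and 1671 of 1953 HSC-like cells, so unlike parts of this class were compared. Without thinning 2.71%, 6.80% and 2.66% of HSC-like cells were positive. Such scores also read free RNA, and no cycling rate is read from them alone.

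Within the 4 classes that had at least 200 cells in each library, the difference between vancomycin and control was again broad and mostly in 1 direction. Of 5549 genes in HSC-like cells 633 were at least 1.5-fold higher and 41 lower. The counts were 625 and 39 of 5351 in lymphoid-primed-like, 420 and 40 of 4947 in granulocyte-monocyte-primed-like and 712 and 47 of 5484 in megakaryocyte-primed-like cells. With median-of-ratios scaling they were 267 and 145, 239 and 174, 200 and 92, and 307 and 132. Vancomycin plus BAP against control gave 53 and 40, 53 and 39, 51 and 34, and 59 and 32 genes in the same classes. Of genes at least 1.5-fold apart between vancomycin and control in 1 class, 97.3% to 99.8% had the same direction in another. In HSC-like cells H2-Aa was 4.00-fold (3.05 to 5.33) higher within a class median shift of 0.19. In megakaryocyte-primed-like cells the retinal dehydrogenase Aldh1a1 was 5.56-fold (4.15 to 7.56) higher. Fcer1a, an IgE receptor chain of basophils and mast cells, was 9.66-fold (6.22 to 15.7) higher there, in a class where 2 vancomycin cells and 0 control cells held at least 20 UMIs of Prss34 and Mcpt8. In granulocyte-monocyte-primed-like cells H2-T23 was 2.45-fold (1.95 to 3.09) higher. Rpl9 was higher with BAP than with vancomycin alone by 2.33-fold (2.19 to 2.49) in HSC-like, 2.33-fold (2.09 to 2.59) in lymphoid-primed-like, 2.25-fold (2.02 to 2.52) in granulocyte-monocyte-primed-like and 2.29-fold (2.12 to 2.48) in megakaryocyte-primed-like cells. Klf2 was at 0.277 (0.254 to 0.303) of vancomycin in HSC-like and 0.316 (0.273 to 0.365) in megakaryocyte-primed-like cells. Immunoglobulin and haemoglobin transcripts were among the most different genes within classes too. In HSC-like vancomycin cells 90.5% of Hbb-bs UMIs were in 1 cell, and Igkc was seen in 49.4% of HSC-like vancomycin cells (median 3892 UMIs) and in 58.6% of T or NK-like ones (5501 UMIs), which should lack it.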

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

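No test was run in this part. Barcodes that failed the filter on detected genes and mitochondrial share were left out of every result, and their number was noted because it means deposited data were not used. They were 13 of 6847 barcodes (0.190%) in the vancomycin library and 11 of 8771 (0.125%) in the vancomycin plus BAP library, beside 1 of 8567 in control. In 6 of the 13 and 7 of the 11, haemoglobin made up over 50% of UMIs, and in 2 and 1 immunoglobulin did, and the 1 control barcode was also mostly haemoglobin. Whether these held red cells and plasma cells or their free RNA was not tested. Too few genes were detected in 8 and 8, and 5 and 3 had too many mitochondrial UMIs. With all deposited barcodes summed, 660 genes were at least 1.5-fold higher and 40 lower in vancomycin against control, close to the 687 and 41 of the kept cells.

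No library was judged as an outlier against others of its group, since each group had 1 library, and no value of a library was corrected or removed.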

How the results depend on the processing

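Most settings were chosen before the data were examined. Those chosen after results were seen are the removal of the B-lineage-like cluster, cells with no positive cycle score, thinned sums, the length and GC correction, the pseudocount, clustering without marker genes, and median-of-ratios scaling for the position and within classes. No paired analysis was possible because the libraries hold pooled cells of different mice with no shared unit between groups. Leaving out a library or splitting samples another way was not possible with 1 library per group.

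The counts of genes depended on scaling and on the expression minimum. In vancomycin against control, 687 genes were higher and 41 lower. Median-of-ratios scaling gave 300 and 108, totals without the most abundant genes 339 and 97, and the length and GC correction 246 and 88. A minimum of 2 CPM gave 1120 and 96, one of 50 CPM 188 and 22, and cells with no positive cycle score gave 77 lower genes. In vancomycin plus BAP against control (73 and 27), the minimum of 2 gave 225 and 66, that of 50 gave 21 and 14, and cells with no positive cycle score 41 lower genes. In vancomycin plus BAP against vancomycin (52 and 760), median-of-ratios scaling gave 112 and 337, reduced totals 106 and 353, and the length and GC correction 95 and 263, while the minimum of 2 gave 117 higher genes and that of 50 gave 27 and 218. In each of these settings more genes were higher than lower in vancomycin against control, and more lower than higher in vancomycin plus BAP against vancomycin. The pseudocount of 0.1 CPM gave 680 and 41, 71 and 27, and 52 and 750 for the 3 comparisons. Of 84 alternative counts, 59 stayed within 1.5 times the first value and 25 moved further.

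Of 105 alternative differences in class shares, 66 stayed within the counting interval of the first value, 31 moved and 8 turned direction. A turn was counted where the interval of the first value left out 0, and 6 more values changed sign without meeting that rule, so 14 changed sign. The HSC-like share was 10.7 points higher in vancomycin than in control, and 8.49 at resolution 0.6, 2.87 at resolution 1.6, 4.89 without cell cycle genes, 4.59 with the clusters of the control library, 1.23 with doublet-like barcodes, 1.6 with stricter filters and 3.97 without marker genes. For vancomycin plus BAP against control the 8.71 points became 4.01 at resolution 1.6, 5.39 without cell cycle genes, 6.03 with control clusters, 4.06 with doublet-like barcodes, 3.78 with stricter filters and 4.87 without marker genes. Between the exposed libraries, the difference of -1.99 points for BAP turned to 1.14, 0.501, 1.44, 2.83, 2.18 and 0.908 in these same 6 settings, so which exposed library held more HSC-like cells is open.

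The lymphoid-primed-like share differed by -1.62 points in vancomycin against control, and by -2.64 without cell cycle genes, -0.177 with doublet-like barcodes, -0.551 with stricter filters and -0.344 without marker genes. For vancomycin plus BAP the 0.496 points against control became -1.91 with control clusters, and the 2.11 points against vancomycin became -1.09 with control clusters, 1.14 with doublet-like barcodes and 0.414 without marker genes. Granulocyte-monocyte-primed-like cells differed by -0.644 points in vancomycin against control, by -1.47 without cell cycle genes and by -11.3 without marker genes. With BAP the -1.80 points against control became -2.71 and -6.12 in these settings, and the -1.16 points against vancomycin became 5.19 without marker genes. Without marker genes this class held 22.2% of control cells instead of 4.70%, so it was not the same set of cells. Megakaryocyte-primed-like cells differed by 0.879 points in vancomycin against control, by -0.583 at resolution 0.6, -0.960 without cell cycle genes and -0.910 with stricter filters. Against control the BAP library differed by -0.783, and by -2.46 without cell cycle genes, -2.22 with control clusters, -2.05 with stricter filters and -1.80 without marker genes. The erythroid-primed-like differences of -1.42, -1.21 and 0.213 points stayed close in the 7 alternatives.

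The share of cells with a positive cycle score moved with each setting. It was 57.0%, 61.6% and 48.0% in control, vancomycin and vancomycin plus BAP, and 50.6%, 59.0% and 45.6% without thinning and 40.9%, 51.3% and 34.2% with scores over 0.1, in the same order of libraries. Within HSC-like cells it was 4.67%, 9.57% and 4.13%, within lymphoid-primed-like cells 18.7%, 26.2% and 16.5%, within granulocyte-monocyte-primed-like cells 91.6%, 97.7% and 93.6%, within erythroid-primed-like cells 59.8%, 73.2% and 61.9%, and within megakaryocyte-primed-like cells 75.2%, 82.6% and 69.6%. With scores over 0.1 the HSC-like shares were 0.4%, 2.70% and 0.658%. Vancomycin had the highest share in all of these. The order of control and vancomycin plus BAP turned in the granulocyte-monocyte-primed-like and erythroid-primed-like cells, and in HSC-like cells with scores over 0.1. It also turned in cells of the unnamed clusters (66.3% in control and 68.0% with BAP). With scores over 0.1 it turned in lymphoid-primed-like cells (5.74% and 6.17%).

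Of 714 list medians under alternatives, 629 moved by no more than 0.5 times the width of the middle 95% of random lists, 80 moved further, and 5 turned sign. A turn was counted only for a first median outside that range, so 40 more that changed sign from inside it are not counted. Those that turned in vancomycin plus BAP against control were the unfolded protein response, at 0.08 and at -0.0171 after class standardisation and -0.0285 without the B-lineage-like cluster, S phase genes at 0.0208 after class standardisation, and quiescence genes at -0.0023. T and NK lineage genes turned to -0.18 in vancomycin plus BAP against vancomycin. Of 935 ratios of genes named by size 656 stayed within the counting interval of the first value, 276 moved and 3 turned, all of basophil proteases in cells with no positive cycle score. Prss34 stood at a log2 ratio of -1.54 and Mcpt8 at -1.09 in vancomycin against control, and Prss34 at -0.0868 in vancomycin plus BAP against control. Genes given whatever their size are mostly outside the 935, and of these Kit turned from 1.07 to 0.943 times control in vancomycin under median-of-ratios scaling. Under it Kit and Ffar2 also turned in vancomycin plus BAP against vancomycin, from 0.932 to 1.04 and from 0.919 to 1.02. The median position of the vancomycin plus BAP library, 0.0496, was 0.0364 with genes at least 1.3-fold apart, 0.155 with genes at least 2-fold apart, 0.0479 when genes were picked and read out in different cells, 0.0743 after class standardisation, 0.0991 with median-of-ratios scaling and 0.0557 without the B-lineage-like cluster.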

Other observations

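Gene lists were read again within the HSC-like, lymphoid-primed-like, granulocyte-monocyte-primed-like and megakaryocyte-primed-like cells, in that order, to see whether progenitor types carried them alike. All tests on cycling, length and GC, library preparation, free RNA, vancomycin exposure, Xist and the share of genes against the vancomycin plus BAP library were chosen after the results were seen. Immediate early genes, which respond within minutes to growth factors and to handling, had medians of -0.51, -0.49, -0.43 and -0.54 in vancomycin plus BAP against control, lower in each class, and of -0.82, -0.72, -0.65 and -0.72 against vancomycin. Ribosomal protein genes had medians of -0.34, -0.31, -0.27 and -0.37 in vancomycin against control, and MHC class I genes 0.58, 0.65, 0.55 and 0.72, so that neither was limited to one type. Glycolysis genes had medians of 0.49, 0.40, 0.32 and 0.56, and fatty acid oxidation genes 0.44, 0.40, 0.35 and 0.47.

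The medians of each class come from its own set of genes, and no test of a difference between classes was run. In vancomycin against control, S phase genes had medians of 0.51, 0.49, 0.26 and 0.40, and G2 and M phase genes 0.23, 0.24, 0.41 and 0.66, where HSC-like and lymphoid-primed-like cells lay close to their class median (0.04 and 0.06 above it). Granulocyte-monocyte priming, lower in the vancomycin plus BAP library as a whole, had within-class medians of -0.03, -0.03, -0.04 and 0.20 against control, near or above 0. Clusters split by library in the same field: one led by Mcm3, Mcm2 and Ung was nearly confined to vancomycin, while those led by Irf8, Ung and Hells and by Rrm2 and Tk1 held 12.4% and 5.48% of control cells against 1.84% and 0.743% of vancomycin cells. Whether these are the same cells drawn apart by the library or different states was not tested.

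Of the broad difference between vancomycin and control, the upward shift of all genes may come from the smaller share of UMIs on ribosomal protein and other abundant genes, since the all-gene median log2 ratio was 0.0176 once these were left out of the totals. The same scaling took the higher genes from 687 to 339 and the lower ones from 41 to 97, so part of the pattern goes with it, but it argues against these abundant genes as the source of the rest, as vancomycin still had 4.36 times as many genes apart from control as vancomycin plus BAP had (436 against 100). Among cells of 4000 to 6000 UMIs 79.8% of the 687 genes stayed at least 1.5-fold higher, against depth per cell, while thinning, with 90.1% kept, cannot decide because it leaves expected ratios as they are. In cells with no positive cycle score 92.7% stayed at least 1.3-fold higher, and the length and GC correction left 246 higher genes, a number 82% as large as the 300 under median-of-ratios scaling, of which 217 (72.3%) stayed higher, against cycling cells and transcript length as main sources. The 687 genes were picked in all kept cells, which include the cells of the depth and cycling checks. The cycling check also used a lower limit than the 1.5-fold that picked them. At 1.5-fold, 764 genes, not all need be the same, were higher in cells with no positive cycle score, where the all-gene median was 0.16. Preparation or sequencing of the vancomycin library cannot be told apart from the exposure, because 98.1% of genes apart in granulocyte-monocyte-primed-like cells had the same direction in HSC-like cells, which either could give, and with 1 library per group mice, litters, cages and sort days stay untested.

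Immunoglobulin transcripts, 0.0293% of UMIs in control, 1.3% in vancomycin and 0.951% in vancomycin plus BAP, were weighed next. Outside the B-lineage-like cluster, mean UMIs per cell of Igha, Igkc and Jchain summed differed between progenitor classes by up to 1.77-fold in vancomycin and 2.39-fold in vancomycin plus BAP. Single genes could differ more. With BAP, Igha alone had 0.132 UMIs per cell in HSC-like and 0.407 in granulocyte-monocyte-primed-like cells, whose median depths were 3834 and 11614.5 UMIs. Free RNA of plasma cells in the droplets is a candidate explanation that stays open, as the larger value of the sum lay between the 2-fold and 3-fold limits set for it. Igkc was also seen in 71.4% of granulocyte-monocyte-primed-like vancomycin cells (median 11977 UMIs). In the B-lineage-like cluster itself, Mzb1, Xbp1 and Sdc1, which plasma cells express, were found in 100%, 100% and 77.6% of vancomycin cells. Of HSC-like vancomycin cells 0.417%, 27.5% and 1.85% held them. With BAP the cluster had 98.9%, 98.9% and 80.9%, so its cells resembled plasma cells. Whether they were carried over in the sort stays open, since the rule asked for both Kit and Ly6a to be low. Kit was at 0.160 of the level of other cells in vancomycin (0.0912 with BAP). Ly6a, which encodes Sca1, was 58.9-fold and 62.4-fold higher, but plasma cells also express it, so it cannot decide. The B-lineage-like share was 0.885 points higher in vancomycin than in control, which an effect of the exposure or a difference between sorts could give alike.

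Xist was weighed last, since it was present in nearly all cells of libraries described as male. The tables argue against male cells that took up free Xist RNA, since the Y-linked genes had at most 0.159% of the UMIs of their X-linked partners Ddx3x, Eif2s3x, Kdm5c and Kdm6a (the highest upper counting limit of the 3 libraries), although no male library was there to set the scale. They argue in the same way against male cells mixed into the vancomycin library as the source of its lower Xist level, at 0.0731% there, and of its cells thinned to 3000 UMIs 2.16% lacked Xist. Y-linked genes reached at most 0.144 CPM, so a candidate explanation is that the mice were female or that the sex in the design text refers to other animals. What part of the Xist was free RNA in the droplets stays open, as mean Xist UMIs per cell differed between progenitor classes by 1.96-fold in control, 1.76-fold in vancomycin and 2.06-fold in vancomycin plus BAP, and the cause of the lower level in vancomycin was not found.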
